A study of Mus musculus with 6 samples.

How the data were processed

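Total RNA from frozen liver of 6 male mice was labelled with biotin and hybridized to Affymetrix 3′ expression arrays, 1 array per mouse, per the labels' protocols. The labels put 3 arrays in the wild-type group (WT) and 3 in the liver ChREBP knockout group (ChLO), and call the samples within a group biological replicates 1 to 3.

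The authors deposited 1 table of log2 signals, with 45101 probe sets per array. MAS5, Affymetrix's single-array summary, is named in the submitters' processing notes with no version or parameters. The log2 scale and the scaling were worked out from the deposited values. After conversion back to linear signal, the mean of each of the 6 arrays was 500 once 2% of the values had been trimmed from each end, which is what MAS5 global scaling gives. The quantiles differed between arrays, so no quantile normalization had been applied. Scaling of this kind gives every array the same average signal, so a rise or fall shared by most transcripts would not be seen. MAS5 also leaves dim probe sets very variable on the log2 scale, and the lowest value on the array of WT replicate 1 was -2.70. Detection calls and raw scanner files were not used here. No genome build is named in the sources used here and no coordinates are given.

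Probe sets were named through the platform's annotation. Of the 45101 probe sets, 64 were hybridization or labelling controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Entrez identifiers of 99.4% of the probe sets with 1 symbol were found in a mouse gene table, and 0 symbols needed an update. Probe sets with several symbols or none were not given a gene name. Control probe sets were left out, then probe sets whose mean log2 signal over the 6 arrays lay below the 40th percentile, a log2 signal of 5.50 or a linear signal of 45.2. This left 27022 probe sets. Each gene was represented by its probe set with the highest mean over all 6 arrays, chosen without regard to group, and 12598 genes were tested out of 18193 with a named probe set. Probe sets past the filter disagreed in sign with the chosen probe set for 2 of the 87 genes named in the text with a difference or a signal by group, Acly and Dcn.

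Genes were compared between ChLO and WT with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with no block, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. The threshold was an adjusted p of 0.05. Differences are ChLO minus WT on the log2 scale, and SE is the moderated standard error of limma. The p-values measure the spread between the mice within a group. The design, the alternatives and 33 gene lists holding 623 genes (pathways, stress responses, cell type markers, zonation, sex-biased genes and others) were fixed before the data were examined. Of the list genes, 552 had a named probe set and 508 were tested, and some genes stood in several lists, as did 12 of the 22 ChREBP targets. Each list was compared with all other tested genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 33 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way without comparing them with other genes, were alternatives. For single genes of a list, a count adjusted over the list alone is given beside that over all genes tested. The verbs rose and fell are used of single genes that passed over their list alone.

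The text names Mlxipl, the 12 genes that rose most and the 12 that fell most among those past the threshold with no overlap between groups, up to 4 members of each list with the smallest p, and 23 genes fixed in advance whatever their values. No gene passed over all genes tested, so the second part of the rule named none. Of the 23 genes, 4 are not analysed here. Genes outside this rule are named only where the text says that they were chosen after their values were seen.

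Alternatives changed 1 choice at a time. They were quantile normalization, equal array medians, no filter or a 60th percentile filter, eBayes without a trend or with robust fitting, array weights, the mean of all probe sets of a gene, leaving out probe sets that can match several transcripts, the replicate number as a block, leaving out each array in turn, other thresholds, and all probe sets as the unit. Scaling to the hybridization spike-in controls was added after the data were seen. Replicate numbers were shared between the groups, but same-numbered arrays did not deviate together, so the numbers were not taken as pairs.

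The procedure was tested on simulated data with the means and spread of these arrays, 12598 genes and 200 changed genes in each of 20 simulations. It called 19.6% of genes changed by a log2 of 1, 60.9% at 2, 79.5% at 3 and 86.4% at 4, and on average 4.05% of its calls were false. The changed genes were drawn at random from all genes tested. These shares thus need not hold for genes that vary more within a group, such as Fasn (SE 0.94) and Elovl6 (SE 0.66). A list shifted by a log2 of 1 was called in 100% of the simulations, and 0.172% of unchanged lists were called. Simulated genes varied independently of each other, while the correlation estimated within a real list reached 0.616. The shares for lists thus do not give the error rate of the list test on these arrays. Arrays carry no read depth, and the number of arrays, 3 per group, limits the precision. Figures were drawn with matplotlib 3.10.9.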

Results

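Gene expression was measured in the livers of 6 male mice, 3 WT and 3 ChLO. ChLO mice carry floxed alleles of Chrebp, the gene now called Mlxipl, and Cre recombinase under the albumin promoter, which is active in hepatocytes. ChREBP is a transcription factor that carbohydrate activates and that turns on genes of glycolysis and fat synthesis. The mice were 12 weeks old and had eaten a diet with 60% sucrose for 1 week. The comparison asks which liver transcripts differ when ChREBP is deleted in the liver under a sucrose load. Array medians lay between 6.38 and 6.60 log2 units. Correlations between arrays over the 12598 genes tested ran from 0.894 (WT 2 with ChLO 1) to 0.954 (WT 2 with WT 3).

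Mlxipl, the deleted gene, was measured by 1 probe set. Its log2 signal was 12.59 ± 0.03 (SD, n = 3) in WT and 11.01 ± 0.60 (SD, n = 3) in ChLO. ChLO 1, 2 and 3 read 10.34, 11.22 and 11.48, each below the lowest WT array at 12.56. The difference was -1.57 (SE 0.28), 2.98-fold lower, with a limma adjusted p of 0.185 over 12598 genes and 0.00705 adjusted over the list alone, the list being hormone and nutrient signalling. Without ChLO 3 it was -1.81 and passed over all genes (adjusted p = 0.0199). Where the probe set lies relative to the floxed exons is not given in the sources used here, so this reading is not a full check of the labels.

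In ChLO livers on sucrose, most measured ChREBP targets and most genes that build fatty acids had lower signals than in WT livers, and the medians of both lists lay below every WT array in all 3 ChLO arrays. Some single genes of fructose and glucose handling were lower too. Rgs16 was 14.4-fold, Pklr 12.5-fold, Elovl6 12.3-fold and G6pc 9.65-fold lower. Signals of stromal, bile duct, myeloid and stress genes were higher in ChLO 1 and ChLO 2, whereas for most of these ChLO 3 read at the WT level. Oxidative stress genes were an exception, with a median above every WT array in ChLO 1 but not in ChLO 2. The integrated stress response was another. Its median lay above every WT array in all 3 ChLO arrays, at 0.40 in ChLO 3 against 0.27 in WT 1. Over the fixed lists alone, 50 distinct genes passed, of which 43 fell and 7 rose. Without ChLO 3 there were 160, of which 82 fell and 78 rose, without WT 1 there were 33 (29 and 4), and without ChLO 2 there were 39 (35 and 4). Each of the 7 was above every WT array in all 3 ChLO arrays. Of the 43, all were below every WT array in ChLO 2 and ChLO 3 and 40 were in ChLO 1. These genes were chosen by their p in the same arrays, so this separation is largely set by the choice.

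Over all 12598 genes, limma called 0 genes at an adjusted p under 0.05 (smallest 0.0528) and 14 under 0.10, 10 of them lower. At an unadjusted p under 0.05 there were 1129 genes, 688 higher and 441 lower, where chance would give 630. That count was 2575 without ChLO 3, 700 without ChLO 2 and 2013 with spike-in scaling. The groups did not overlap for 1919 genes, or 15.2%, where chance gives 10%. Without ChLO 3 there were 302 calls (201 higher and 101 lower), and without ChLO 1 there were 4. Camera called 21 of the 33 lists, 6 higher and 15 lower. With an estimated correlation it called 0 lists, 5 of them having an unadjusted p under 0.05, and fry called 1, the ChREBP targets.

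**Figure D1:**
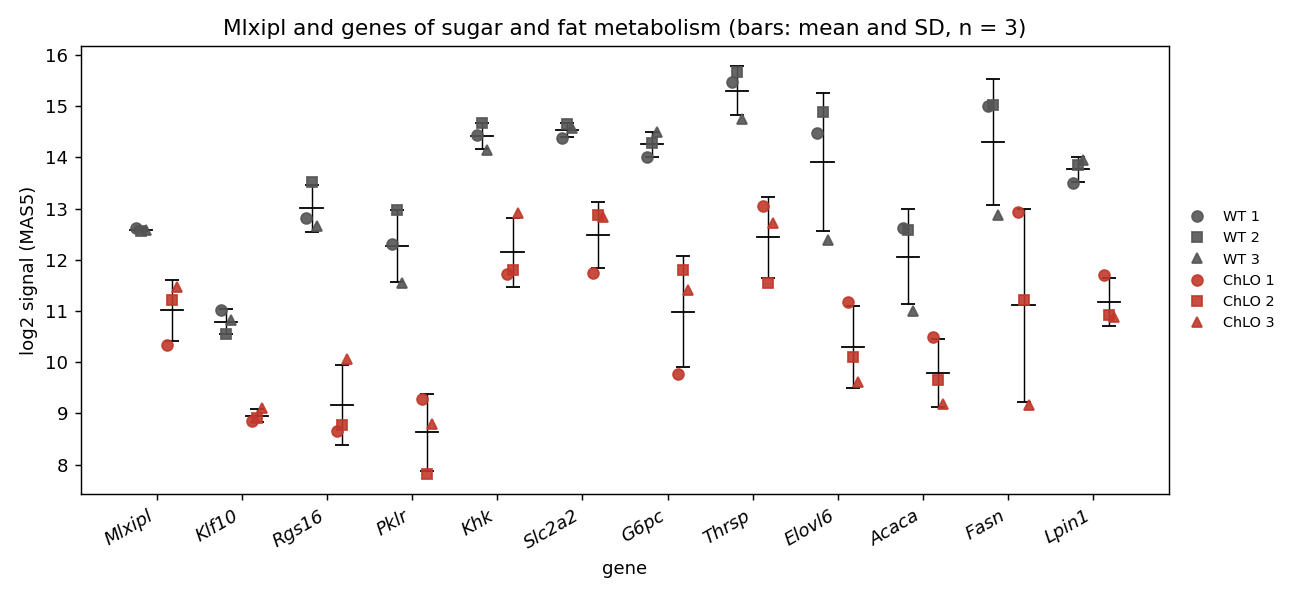
Log2 signal (vertical axis, MAS5 units) of Mlxipl and 11 genes of sugar and fat metabolism (horizontal axis) in the 3 WT arrays (grey) and the 3 ChLO arrays (red), with the marker shape giving the replicate and bars the mean and SD. The ChLO arrays lie below the WT arrays for every gene shown except Fasn, for which ChLO 1 (12.94) lies above WT 3 (12.87).

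Textbook targets of ChREBP were lower as a group, and the list had the smallest camera p of all 33. Of 22 measured targets, 20 had lower signals in ChLO, and 15 fell and 0 rose adjusted over the list alone, against 0 over all genes tested. The number that fell lay between 13 and 17 when each array was left out in turn, and 1 rose without WT 2. Rgs16, a regulator of G protein signalling, fell by 3.84 (SE 0.40), and Pklr, liver pyruvate kinase, fell by 3.64 (SE 0.45). Thrsp, a lipogenic protein also called Spot 14, fell by 2.86 (SE 0.41), and Klf10, a zinc finger repressor, fell by 1.83 (SE 0.19). All 4 were below every WT array in all 3 ChLO arrays. The median over the list was -1.35, and camera gave an adjusted p of 1.06e-21, with an adjusted p of 0.128 with an estimated correlation and 0.0240 by fry. Txnip, an inhibitor of thioredoxin, did not pass at -0.60 (SE 0.47) and read 12.65 in ChLO 3, above every WT array. Fgf21, a liver hormone, read 8.70, 10.59 and 4.01 in the ChLO arrays, with a difference of -0.58 (SE 1.50) that became 1.29 without ChLO 3.

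Of 7 measured genes of fructose uptake and breakdown, 3 fell adjusted over the list alone, in every fit that left out 1 array as well. All 3 also stand in the list of ChREBP targets and were counted there, so they are not a separate result. Khk, the kinase that commits fructose to breakdown, went from 14.42 ± 0.26 to 12.15 ± 0.67 (SD, n = 3 each), a difference of -2.27 (SE 0.33). Slc2a2, the hepatocyte glucose and fructose transporter GLUT2, fell by 2.05 (SE 0.31), and Tkfc, the triose kinase of the same route, at -1.76 (SE 0.31). The list median was -0.47, with a camera adjusted p of 1.60e-05 and an adjusted p of 0.211 with an estimated correlation. In glycolysis 3 of 15 genes fell over the list alone, and beside Pklr they were genes of the pyruvate dehydrogenase step. Pdhb, a subunit of that enzyme, fell by 0.86 (SE 0.18), and Pdk1, a kinase that inhibits it, at -1.52 (SE 0.35). The glycolysis median was -0.07 (camera adjusted p = 0.0159, and adjusted p = 0.356 with an estimated correlation), and the call was lost without ChLO 3 (adjusted p = 0.259), where 2 genes rose and 4 fell. Without ChLO 2 the number that fell was 2, and without ChLO 1, 1 gene rose. The call was also lost with quantile normalization (adjusted p = 0.0719) and array weights (0.114).

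Genes that release glucose from the liver were lower too, mostly in ChLO 1, with list medians of -1.23, -0.40 and -0.12 from the WT mean in ChLO 1, 2 and 3 and -0.12 in WT 1. In gluconeogenesis 11 of 13 genes were lower and 4 fell adjusted over the list alone, with between 2 and 7 when an array was left out and 7 without ChLO 3. G6pc, the catalytic subunit of glucose-6-phosphatase, fell by 3.27 (SE 0.48), and Slc37a4, its glucose-6-phosphate transporter, at -1.35 (SE 0.38). Fbp1, fructose-1,6-bisphosphatase, fell by 1.27 (SE 0.36) and Pcx, pyruvate carboxylase, at -0.91 (SE 0.16). The count was 2 without WT 1, WT 2, WT 3 or ChLO 2. The list median was -0.64, the camera adjusted p 5.87e-06, and the adjusted p 0.398 with an estimated correlation. For glycogen, 1 of 17 genes fell over the list alone, Pygl, the liver glycogen phosphorylase, at -1.46 (SE 0.22), and 2 fell without WT 3, ChLO 2 or ChLO 3, with 1 that rose without ChLO 3. Gys2, liver glycogen synthase, did not pass at -0.75 (SE 0.56). The glycogen list had a median of -0.35 and a camera adjusted p of 0.00520, with an adjusted p of 0.264 with an estimated correlation. By array its median was -0.19, -0.14 and -0.07 in ChLO 1, 2 and 3 and -0.10 to 0.09 in WT, so ChLO 3 lay within the WT range. In the pentose phosphate pathway 1 of 9 genes rose, Prps2, a phosphoribosyl pyrophosphate synthetase, by 1.07 (SE 0.26), and the number that rose was 0 without WT 1, WT 3, ChLO 2 or ChLO 3, with 1 that fell without WT 3. That list was not called (camera adjusted p = 0.859), and its median of 0.02 and mean of -0.04 differ in sign.

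Fatty acid synthesis showed the lowest list median, -1.60, with 17 of 18 genes lower and 15 that fell adjusted over the list alone. Elovl6, which elongates fatty acids, fell by 3.62 (SE 0.66), Fasn, fatty acid synthase, at -3.19 (SE 0.94), and Acacb and Acaca, the acetyl-CoA carboxylases, at -2.81 (SE 0.58) and -2.28 (SE 0.49). Elovl5, a second elongase, fell by 1.77 (SE 0.29), Acly, ATP citrate lyase, at -1.71 (SE 0.53), and Srebf1, the lipogenic transcription factor SREBP-1, at -1.19 (SE 0.32). A dim probe set of Acly (mean 5.82) was higher in ChLO by 1.17, unlike the 4 others past the filter. Scd1, stearoyl-CoA desaturase, fell by 0.72 (SE 0.23) on a probe set near the top of the arrays' range (14.97 to 16.05), while its other probe set past the filter, with a mean of 13.32, differed by -2.28. Arrays of the same genotype were far apart, with Fasn at 15.00, 15.02 and 12.87 in WT and 12.94, 11.22 and 9.16 in ChLO. Camera gave an adjusted p of 2.95e-19, and the adjusted p was 0.211 with an estimated correlation. The count of 15 became 9 without WT 1 and 9 without WT 2.

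In triglyceride synthesis, lipid droplets and VLDL, 16 of 21 genes were lower and 3 fell adjusted over the list alone. Lpin1, which makes the diacylglycerol used for triglyceride, fell by 2.60 (SE 0.26). Mttp, which loads lipid onto lipoproteins, fell by 1.09 (SE 0.20), and Agpat2, an acyltransferase, at -0.86 (SE 0.21). The count was 6 without ChLO 3, 6 without WT 3 and 5 without ChLO 1, and 2 in the other fits that left out an array. The list median was -0.47 (camera adjusted p = 4.82e-07, and adjusted p = 0.249 with an estimated correlation). In cholesterol synthesis and uptake, 2 of 21 genes fell, Stard4, a sterol carrier, at -0.90 (SE 0.15) and Aacs, acetoacetyl-CoA synthetase, at -2.03 (SE 0.50), and the count was 0 without ChLO 2 and 1 without WT 1, WT 2 or ChLO 3. Msmo1, an enzyme of sterol synthesis, was higher by 0.80 (SE 0.22) without passing, and 1 gene of the list rose without WT 2. The cholesterol median was -0.12 (camera adjusted p = 0.0241, and adjusted p = 0.608 with an estimated correlation). The call ended without WT 1 (adjusted p = 0.651), WT 2 (0.107) or ChLO 3 (0.462), and with quantile normalization (0.0853) or array weights (0.189).

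Of 23 genes of bile acid synthesis and transport, 1 rose and 2 fell adjusted over the list alone. Abcc3, an export pump on the blood side of hepatocytes, rose by 1.32 (SE 0.25). Abcb11, the bile salt export pump, fell by 1.26 (SE 0.33), and Nr0b2, the nuclear repressor SHP, at -0.91 (SE 0.22). Without ChLO 3 the counts were 3 and 12, 1 and 3 without ChLO 1, 1 and 0 without WT 1, and 0 and 0 without WT 2, WT 3 or ChLO 2. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.94 (SE 1.20) with WT values of 8.16, 12.16 and 12.13, and by -0.39 without WT 1. The list median was -0.49 (camera adjusted p = 0.00255, and adjusted p = 0.429 with an estimated correlation), and the call ended without ChLO 1 (adjusted p = 0.118). By array it was -1.12, -0.44 and 0.17 in ChLO 1, 2 and 3 and -0.24 to 0.20 in WT, so ChLO 3 lay within the WT range. In fatty acid oxidation 0 of 26 genes passed. The smallest p there was that of Fabp1, the liver fatty acid binding protein, at -0.62 (SE 0.28). That list had a median of -0.14 and was not called (camera adjusted p = 0.242), but was called lower without ChLO 2 (adjusted p = 0.00362) or WT 2 (0.0186) and higher without ChLO 1 (0.0170). Of drug metabolism genes, Abcc3 rose and Cyp2c29, a cytochrome P450, fell by 1.72 (SE 0.35) out of 22. The counts were 0 and 0 without WT 2, 2 and 1 without WT 3, and 1 and 3 without ChLO 3. That list was not called (camera adjusted p = 0.444), and its median of -0.06 and mean of 0.03 differ in sign.

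Genes of the stroma, bile ducts, myeloid cells and stress responses stood higher in ChLO as lists, but few single genes passed. Camera called these 6 lists with its preset correlation and 0 of them with an estimated correlation (adjusted p from 0.398 to 0.608). ChLO 1 differed from WT in all these groups, and ChLO 3 did so for few of the genes. The list median in ChLO 3 lay above every WT array only for the integrated stress response, at 0.40 against 0.27 in WT 1. ChLO 2 differed in all but the oxidative stress list (NRF2 targets), whose median was 0.34 there against 0.44 in WT 1. Krt8, a keratin of epithelial cells, read 15.34, 14.51 and 12.48 in ChLO 1, 2 and 3 and 12.86, 12.17 and 12.44 in WT. Its partner Krt18 read 15.18, 14.24 and 12.08 in ChLO and 12.25, 12.05 and 12.31 in WT. Both keratins were already high in WT livers, unlike Cldn4 of the same list (5.33, 6.10 and 4.71 in WT). Their higher signal thus cannot be assigned to bile duct cells. Over the 96 distinct members of the 6 lists called higher, the median difference from the WT mean was 1.38 in ChLO 1, 1.15 in ChLO 2 and -0.09 in ChLO 3, and 0.20, -0.09 and -0.13 in the WT arrays. The median of hepatocyte identity genes was lower in the same arrays, at -0.42, -0.42 and -0.12 in ChLO 1, 2 and 3. The log2 difference between the 3′ and the 5′ probe sets of Actb, a sign of RNA integrity and labelling, was 0.84, 1.03 and 1.46 in ChLO 1, 2 and 3 and 1.13, 1.38 and 1.28 in WT. For Gapdh it ranged from -0.31 to -0.13 over the 6 arrays, with -0.25, -0.20 and -0.14 in ChLO 1, 2 and 3.

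**Figure D2:**
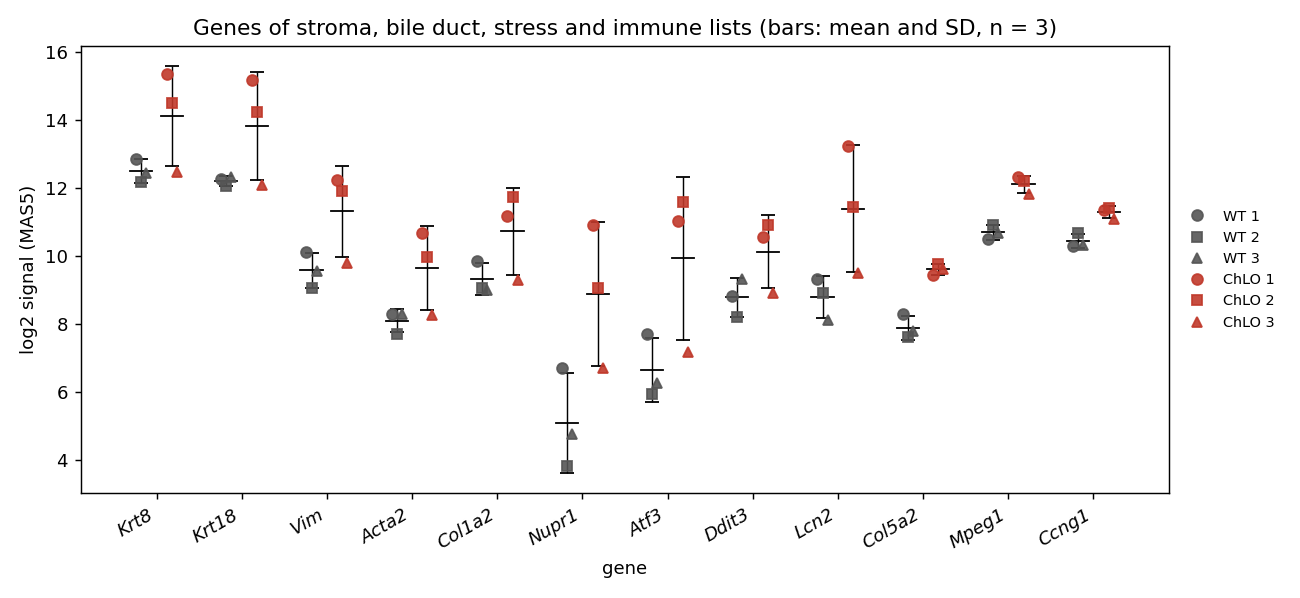
Log2 signal (vertical axis, MAS5 units) of 12 genes of the stromal, bile duct, stress and immune lists (horizontal axis) in the 3 WT arrays (grey) and the 3 ChLO arrays (red), with the marker shape giving the replicate and bars the mean and SD. ChLO 3 lies apart from ChLO 1 and ChLO 2 for genes such as Krt8 (12.48 against 15.34 and 14.51), and with them for Col5a2 (9.61 against 9.45 and 9.78).

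Of 20 genes of stellate cells and fibrosis, 19 were higher and 1 rose adjusted over the list alone, Col5a2, a fibrillar collagen, by 1.72 (SE 0.24). Acta2, smooth muscle actin, differed by 1.54 (SE 0.56), Vim, vimentin, by 1.74 (SE 0.61), Col1a2 by 1.41 (SE 0.58) and Col1a1 by 1.20 (SE 0.54), without passing. The median was 0.77 (camera adjusted p = 4.59e-05, and adjusted p = 0.429 with an estimated correlation). Of 17 genes of infiltrating myeloid cells and chemokines, 15 were higher with a median of 1.55 and 0 passed, or 1 without WT 3. Ccl2, a monocyte chemokine, read 10.30, 9.08 and 6.15 in ChLO and 3.44, 1.25 and 6.27 in WT, a WT mean under the filter level of 5.50. Trem2, a macrophage receptor, lay near that level, at 3.98, 5.93 and 4.54 in ChLO and 6.27 to 6.53 in WT. Camera gave that list an adjusted p of 4.20e-04, with an adjusted p of 0.432 with an estimated correlation. Of 11 genes of cholangiocytes and progenitor cells, 9 were higher and 0 passed. Cldn4, a tight junction protein, had the smallest p and read 9.95, 8.09 and 6.33 in ChLO against a WT mean of 5.38, which is under the filter level. The median was 0.76 (camera adjusted p = 0.0132, and adjusted p = 0.432 with an estimated correlation), and the call ended without ChLO 2 (adjusted p = 0.0683), with spike-in scaling (0.125) and without probe sets of several transcripts (0.123). Without ChLO 3, the numbers that rose over the list alone were 13 of 20, 13 of 17 and 6 of 11.

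Of 17 genes of the integrated stress response, 16 were higher and 0 passed adjusted over the list alone. Nupr1, a stress-induced nuclear protein, read 10.91, 9.07 and 6.70 in ChLO and 6.72, 3.83 and 4.75 in WT, a WT mean under the filter level, and Atf3, a stress transcription factor, read 11.02, 11.58 and 7.19 in ChLO and 7.71, 5.94 and 6.28 in WT. Trib3 differed by 2.04 (SE 0.62), Asns, asparagine synthetase, by 1.96 (SE 0.67) and Ddit3, which encodes CHOP, by 1.34 (SE 0.52). The median was 0.65 (camera adjusted p = 0.00101, and adjusted p = 0.429 with an estimated correlation). In the p53 list 13 of 14 genes were higher and 1 rose, Ccng1, cyclin G1, by 0.85 (SE 0.18), a count that was 0 without WT 1, WT 3, ChLO 1 or ChLO 2, while Btg2 differed by 1.49 (SE 0.49). The median was 0.74 (camera adjusted p = 9.46e-04, and adjusted p = 0.398 with an estimated correlation). Among NRF2 targets 14 of 18 were higher and 1 rose, Gsta2, a glutathione transferase, by 2.18 (SE 0.42), a count that was 0 without WT 2 or WT 3. Nqo1, a quinone reductase, differed by 0.84 (SE 0.34). The median was 0.65 (camera adjusted p = 0.0131, and adjusted p = 0.608 with an estimated correlation), and the call ended without ChLO 1 (adjusted p = 0.460), WT 2 (0.173) or WT 3 (0.0570), and with spike-in scaling (0.0631). Without ChLO 3, the numbers that rose over the list alone were 8 of 17, 10 of 14 and 9 of 18.

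Genes of the unfolded protein response were lower as a list, with 16 of 20 lower by small amounts and 0 past the test. Per array the list median was 0.02, -0.09 and -0.41 in ChLO 1, 2 and 3 and 0.08, -0.22 and 0.24 in WT. ChLO 3 alone thus lay below every WT array, while ChLO 1 and ChLO 2 lay within the WT range. Edem1 differed by -0.40 (SE 0.17). The median was -0.13 (camera adjusted p = 0.0230, and adjusted p = 0.608 with an estimated correlation), and the call ended without WT 1 (adjusted p = 0.114), WT 3 (0.469) or ChLO 3 (0.739), and with quantile normalization (0.219), spike-in scaling (0.125) or array weights (0.147). In the cell cycle list 16 of 19 genes were higher with a median of 0.45, among them Cdk1 at 1.21 (SE 0.66), and 0 passed. It was not called (camera adjusted p = 0.132), but was called higher without WT 1 (adjusted p = 0.00150) or ChLO 3 (8.93e-04, where 2 genes rose) and with array weights (0.00374). In the acute phase response 1 of 22 genes rose over the list alone, Il1rn, the interleukin 1 receptor antagonist, by 1.99 (SE 0.34), a count that was 0 without WT 1, WT 2 or ChLO 2, 2 without ChLO 1 and 6, with 2 that fell, without ChLO 3. Lcn2, lipocalin 2, read 13.25, 11.44 and 9.50 in ChLO and 9.33, 8.90 and 8.12 in WT, and Orm1, an abundant plasma protein, differed by -0.58 (SE 0.16). That list was not called (camera adjusted p = 0.652), and its median of -0.15 and mean of 0.30 differ in sign.

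Among resident immune and vessel cells, 1 of 16 genes of Kupffer cells and macrophages rose over the list alone, Mpeg1, a macrophage perforin, by 1.42 (SE 0.20), to 12.11 ± 0.25 from 10.70 ± 0.21 (SD, n = 3 each). Of the 16 genes, 10 were higher and 6 lower, and 2 of the lower genes had all ChLO arrays below all WT arrays without passing. Adgre1, which encodes F4/80, differed by 0.14 (SE 0.23) and by -0.03 without ChLO 2. Without ChLO 3, 3 genes of that list rose and 1 fell. Its median was 0.12 (camera adjusted p = 0.495, and 0.00779 with array weights). Genes of sinusoidal endothelium had a median of 0.17 with 0 of 16 past the test (camera adjusted p = 0.320, and 0.0221 with array weights), and 1 rose without ChLO 3. Fcgr2b, an Fc receptor, had the smallest p at 0.60 (SE 0.23), but its 3 other probe sets past the filter differed by 0.06, 0.08 and 0.09. For lymphocytes 0 of 7 passed, with a median of 0.07 that camera, which compares with other genes, placed in the lower direction (adjusted p = 0.995). For erythroid cells 0 of 7 passed, with a median of -0.13 and Alas2 at -1.01 (SE 0.46) (camera adjusted p = 0.138), and 1 fell without ChLO 3. For pancreas, fat, muscle and other tissue carried over, 0 of 7 passed, with a median of 0.04 and a mean of -0.31 (camera adjusted p = 0.211).

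Genes of hepatocyte identity were slightly lower, 20 of 20, with a median of -0.32 and 0 past the test, or 2 that fell without ChLO 3. Asgr1, the asialoglycoprotein receptor, differed by -0.83 (SE 0.28). Alb, albumin, differed by -0.19 (SE 0.19), and by 0.12 with quantile normalization and 0.06 with spike-in scaling. Camera gave the list an adjusted p of 2.18e-07, with an adjusted p of 0.429 with an estimated correlation, and the call ended with quantile normalization (adjusted p = 0.0576), where the median was -0.07. Per array the median difference from the WT mean was -0.42, -0.42 and -0.12 in ChLO 1, 2 and 3. Periportal genes had a median of -0.44 with 0 of 14 past the test, but 2 rose and 8 fell without ChLO 3. Their medians were -0.82, -0.54 and 0.02 in ChLO 1, 2 and 3 and -0.04, 0.09 and -0.03 in WT. Etnppl, a phospholyase, read 8.31, 9.37 and 11.81 in ChLO and at least 12.06 in WT. That list had a camera adjusted p of 0.00177, with an adjusted p of 0.429 with an estimated correlation. Among pericentral genes 1 of 17 fell, Cyp2c29, a count that was 0 without WT 1, WT 2 or WT 3, and 1 rose without ChLO 1 or ChLO 3, while Cyp1a2, another cytochrome P450, differed by 0.75 (SE 0.24). That list had a median of 0.19 (camera adjusted p = 0.452) and was called higher without ChLO 1 (adjusted p = 0.00163).

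Of 18 male-biased genes, 15 were lower and 1 fell over the list alone, Serpina12, the serpin vaspin, at -3.61 (SE 0.42), to 9.93 ± 0.89 from 13.54 ± 0.38 (SD, n = 3 each). The median was -0.56 (camera adjusted p = 1.48e-04, and adjusted p = 0.429 with an estimated correlation), and without ChLO 3 the number that fell was 6. Per array the median was -1.45, -0.36 and 0.07 in ChLO 1, 2 and 3 and -0.44, -0.13 and 0.53 in WT, so ChLO 1 alone lay below every WT array. Female-biased genes had a median of 0.06 with 0 of 11 past the test (camera adjusted p = 0.948), or 1 that fell without WT 3 or ChLO 3, and Cyp17a1, a steroid hydroxylase, differed by -2.81 (SE 0.81). Of 15 clock genes 1 fell, Nfil3, at -1.22 (SE 0.27), a count that was 0 without WT 1, WT 3, ChLO 2 or ChLO 3, with 1 that rose without WT 3, while Nr1d1 read 7.15, 6.72 and 7.21 in ChLO and 4.25, 4.67 and 6.71 in WT, a WT mean under the filter level. The clock list had a median of -0.28 (camera adjusted p = 0.00285, and adjusted p = 0.314 with an estimated correlation). By array it was -0.62, -0.20 and -0.05 in ChLO 1, 2 and 3 and -0.08 to 0.11 in WT, so ChLO 3 lay within the WT range. Of 25 genes of hormone and nutrient signalling 3 fell, which were Lpin1, Mlxipl and Lepr, the leptin receptor, at -1.96 (SE 0.41), and 2 fell without WT 1. That list had a median of -0.30 (camera adjusted p = 1.66e-04, and adjusted p = 0.318 with an estimated correlation). Its medians were -0.66, -0.16 and -0.12 in ChLO 1, 2 and 3, with ChLO 3 just inside the WT range of -0.12 to 0.18.

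**Figure D3:**
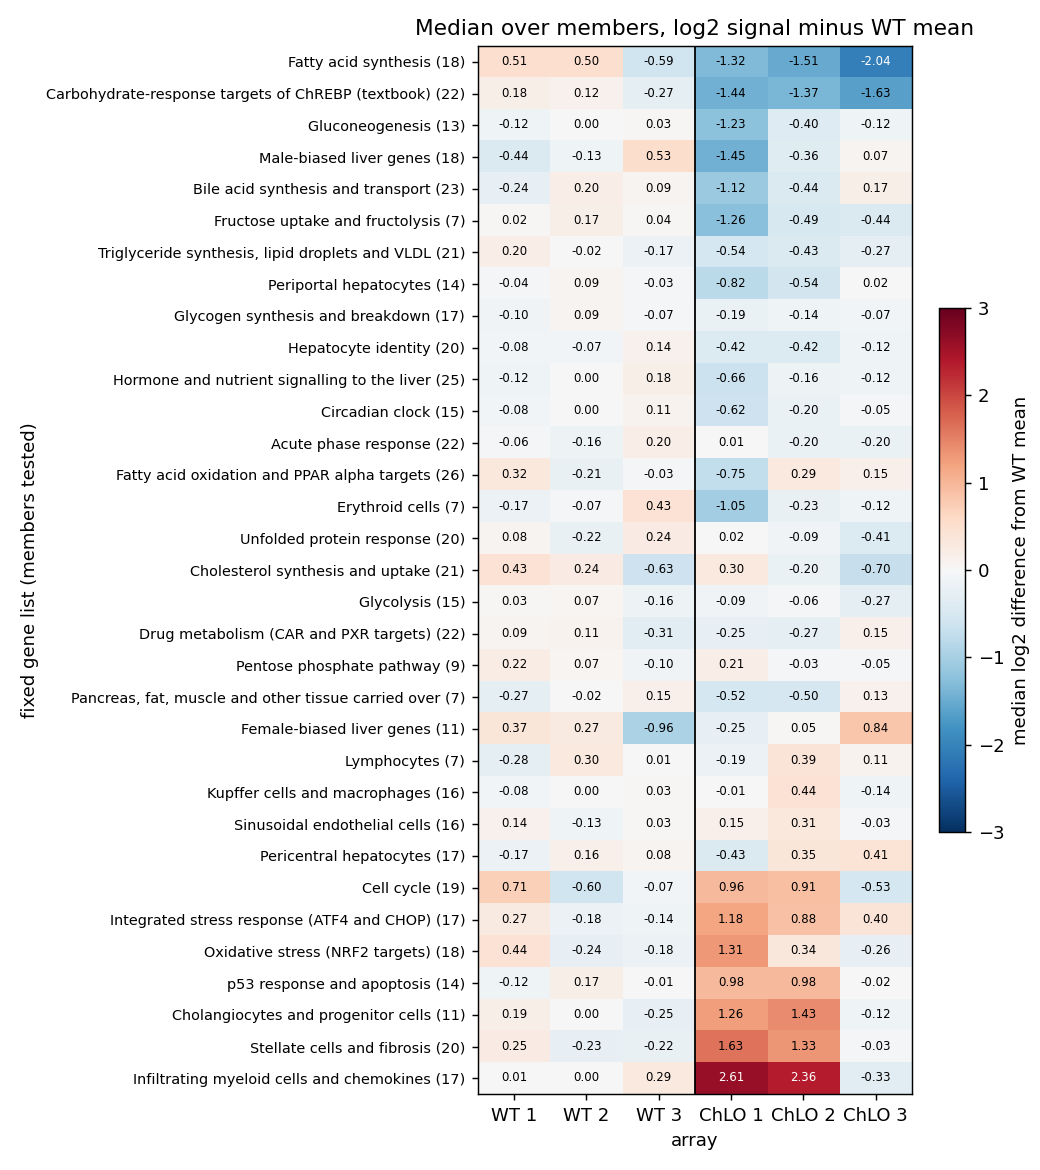
Median over the members of each of the 33 fixed lists (rows, with the number of members tested) of the log2 signal minus the WT mean, for each array (columns). Fatty acid synthesis and the ChREBP targets are at -1.32 or lower in all 3 ChLO arrays, and the myeloid list reads 2.61, 2.36 and -0.33 in ChLO 1, 2 and 3.

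The mean signal of the hybridization spike-in controls was 12.59, 12.49 and 12.78 in ChLO 1, 2 and 3 and 12.83 to 12.90 in WT. With arrays scaled to these controls, the median difference of all genes moved from 0.06 to 0.31, and list medians shifted with it, those of glycolysis, cholesterol synthesis and the unfolded protein response to 0.18, 0.13 and 0.12, still below the median of all genes.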

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

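Every test of an explanation given here was chosen after the pattern had been seen.

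A probe set with no gene symbol in the annotation lay outside the tests by gene and carried a signal that differed between the groups. It read 9.34 ± 0.18 (SD, n = 3) in WT and 11.15 ± 0.21 (SD, n = 3) in ChLO, a difference of 1.81 (SE 0.19) with a limma adjusted p of 0.0415 over 27022 probe sets, but it did not pass when adjusted over the 4273 probe sets without a single gene name alone, and all 3 ChLO arrays were above all WT arrays. Groups of 3 were too small for a search for outlying samples.

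The 6 lists that stood higher in ChLO had medians above every WT array in ChLO 1. The same held in ChLO 2 except for NRF2 targets, at 0.34 against 0.44 in WT 1. In ChLO 3 only the integrated stress response had a median above the WT mean. At 0.40 it was also above every WT array (0.27 in WT 1, the highest). For this pattern 3 technical explanations were tested, and RNA integrity was not among them. A mislabelled WT liver as ChLO 3 is argued against by the ChREBP targets. Their median in ChLO 3 was -1.63 from the WT mean, with 18 of 22 below every WT array. Each WT array against the others gave 0.27, 0.18 and -0.41. Over all genes tested, though, ChLO 3 correlated more with the WT arrays (mean 0.946) than with the other ChLO arrays (0.915). The reverse held for ChLO 1 (0.908 and 0.925) and ChLO 2 (0.935 and 0.941). Array scaling is argued against because the gap between ChLO 3 and the nearer of the other ChLO arrays stayed at 1.21 or more under 3 scalings, against an SD between WT arrays of at most 0.27 under any of them. A lower share of hepatocytes, which would raise the markers of all other cells alike, is argued against as the whole cause because stellate and fibrosis genes exceeded endothelial genes by a mean of 0.69 (permutation p = 2.10e-04 across genes, which are not independent replicates). The stellate list was among those called higher and the endothelial list was not, so the test was not independent of the calls. Per array the stellate mean was 1.37, 1.43 and -0.23 from the WT mean in ChLO 1, 2 and 3, and the endothelial mean 0.12, 0.37 and -6.4e-04. But the abundant stellate genes Dcn, Reln and Ecm1, the last 2 named after their values were seen, differed by only 0.28 (SE 0.29, with a dim second probe set at -0.62), 0.26 (SE 0.23) and 0.04 (SE 0.25), like the endothelial mean of 0.16. Hepatocyte identity genes were lower with medians of -0.42, -0.42 and -0.12 in ChLO 1, 2 and 3 (over the group -0.32, but -0.07 with quantile normalization). A shift of cell shares as part of the cause thus stays open. RNA integrity stays open too, because the 3′ minus 5′ difference of Actb split the ChLO arrays in the same way. It was below every WT array (1.13 to 1.38) in ChLO 1 (0.84) and ChLO 2 (1.03). In ChLO 3 (1.46) it was above every WT array. For Gapdh the ChLO arrays lay within the WT range. Differences in injury between single mice, or between the pieces of liver taken, may also remain. No biological explanation was tested because the labels give none within the ChLO group.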

How the results depend on the processing

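Spike-in scaling was chosen after the data were seen, and the other alternatives before. The count of genes past the threshold, 0, stayed at 0 with the other normalizations, the stricter filter, the other eBayes fits, both other probe set rules and a 2-fold minimum. It was 3 with no filter (Klf10, Lpin1 and Rgs16), 568 with array weights (330 higher, 238 lower), where ChLO 2 had a weight of 4.58 and ChLO 3 of 0.371, 14 at an adjusted p under 0.10 and 8 with probe sets as the unit, and it ranged from 0 to 302 when an array was left out. The estimation of array weights stopped with a convergence warning, so the 568 calls and the array-weight values given for Mlxipl, Fgf21 and the lists rest on weights that had not converged. Without ChLO 1 the 4 genes were G6pc, Lpin1, Serpina12 and Slc2a2. All 14 genes under 0.10 were among the 302 called without ChLO 3 and the 568. With the replicate number as a block, 1 gene passed, Me1, named after its value was seen. Same-numbered arrays had correlations of 0.304, -0.166 and 0.0631 and only number 1 correlated best with its own, so the numbers were not read as pairs. The Mlxipl difference was -1.43 with array weights (adjusted p = 0.0165) and ranged from -1.81 to -1.24 over the left-out arrays, and over all its alternatives the adjusted p ranged from 0.0165 to 0.614.

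The 21 lists called became 0 with an estimated correlation and 1 by fry, and of the 21, 14 kept call and direction in all 17 refits with the preset correlation. The glycolysis call also ended with the replicate number as a block (adjusted p = 0.0682), and the cholangiocyte list was too small to test with the 60th percentile filter. The mean of the fatty acid oxidation list was 0.36 without ChLO 1 and -0.30 without ChLO 2, the ends of its range over the left-out arrays. Of 86 named genes besides Mlxipl, 6 changed sign somewhere. Fgf21 was at 1.68 with array weights, 0.15 without WT 1 and from -2.00 (without ChLO 2) to 1.29 (without ChLO 3), Cyp7a1 from -0.39 (without WT 1) to 1.75 (without ChLO 1), Adgre1 from -0.035 (without ChLO 2) to 0.27 (without WT 2), and Alb at 0.12 with quantile normalization and 0.061 with spike-in scaling. Dcn was at -0.17 with the mean of its probe sets, and Ecm1 ranged from -0.16 (without WT 3) to 0.21 (without WT 2), and was at -0.12 without ChLO 2. Other causes than the number of arrays or genes were not tested. The pseudocount alternatives were not run because the values were already log2, and Mlxipl had no value once probe sets of several transcripts were left out. Genes with a mean signal under the filter level of 45.2 were tested in the fit with no filter.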

Other observations

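The tests of sterol genes and of array scaling given here were chosen after the pattern had been seen, and those of other splits before.

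Genes outside the fixed lists also differed in all 3 ChLO arrays, and 7 of the 14 genes with an adjusted p under 0.10 are named here after their values were seen. Slc30a10, a manganese exporter, was lower by a log2 difference of -2.56 (SE 0.31), Adipor2, an adiponectin receptor, by -1.17 (SE 0.16), and Mpp4, a scaffold protein, by -1.94 (SE 0.24). Gapdhs, the sperm form of a glycolytic enzyme, read 7.98 to 8.54 in WT and a mean of 4.95 in ChLO, under the filter level of 5.50, so the size of its difference is uncertain. Serpina4-ps1, a serpin pseudogene whose probes can match other transcripts, was lower at -3.73 (SE 0.50). Osbpl3, an oxysterol-binding protein, read 9.59, 10.13 and 9.13 in ChLO against a WT mean of 5.41, also under that level. Slc16a10, a transporter of aromatic amino acids, was higher at 1.36 (SE 0.18), and its 3 other probe sets past the filter by 0.68 to 0.90. Their limma adjusted p lay between 0.0892 and 0.0977, and each had its 3 ChLO values on 1 side of its 3 WT values. That separation is largely set by choosing them on their p in the same arrays.

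Lipogenic genes also differed between livers of the same genotype, and the median of fatty acid synthesis genes, with the member shared with the cholesterol list left out, was 0.51, 0.52 and -0.54 from the WT mean in WT 1, 2 and 3 and -1.35, -1.41 and -1.90 in ChLO 1, 2 and 3. Array scaling is argued against, since the range of the full list between WT arrays was 1.09 as deposited and 1.10 or more under 3 other scalings. A candidate explanation is variation shared with sterol genes, such as recent feeding, for which the labels give no record. Over the 6 arrays, within-genotype deviations of both lists had a Pearson r of 0.92 (exact permutation p = 0.0833, adjusted 0.167) and a Spearman rho of 0.83 (exact permutation p = 0.139, adjusted 0.278), and the other of the 2 relations tested, with the remaining ChREBP targets, had an r of 0.53 (exact permutation p = 0.611) and a rho of 0.37 (exact permutation p = 0.667). With 36 regroupings the smallest p is 0.0278, and without the 2 arrays farthest from the median the first r was 0.15, so it rests on those arrays and the question stays open.

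Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split called 0 genes and the highest other 1, and with a real count of 0 all 10 splits reach it by construction. For lists the real split called 21 and the highest other 22 (WT 1, WT 2 and ChLO 3 against the rest), and 2 of the 10 splits, the real one included, called at least 21. The split of WT 1, ChLO 1 and ChLO 2 against the rest had 2093 genes at an unadjusted p under 0.05, against 1129 for the real split, which points to a structure of the samples besides genotype.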
